A study of Caenorhabditis elegans with 11 samples.

How the data were processed

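RNA sequencing libraries were available from 11 samples of whole L4 larvae of Caenorhabditis elegans, in 4 genotypes. Wildtype, atfs-1(null) and the double mutant atfs-1(null);nhr-180(cmh19) had 3 samples each, and nhr-180(cmh19) had 2. Per the labels, the animals were fed the HT115 strain of E. coli, RNA was extracted with Trizol, and the libraries were strand-specific and read from both ends. The samples are named by genotype and replicate number, which the labels call biological replicates; they name no shared day or batch. The nhr-180 samples carry the replicate numbers 2 and 3.

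The deposited count table gave unnormalised counts per gene for 46926 genes, of which 22640 had no count in any library. Counting was done with featureCounts 1.5.2, per the submitters' processing notes. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, and near-identical copies such as vit-3, vit-4 and vit-5, the hsp-16 genes and the msp genes, carry uncertain counts. Of the gene identifiers, 46920 were found in the WBcel235 annotation and 46863 of them had the same start and end; gene symbols are those of the deposited count table. The deposited TPM table, length-normalised by the authors, held 18798 genes, those with a summed count of at least 10, and each of its columns summed to 1000000. Both tables come from the same reads. Protein-coding genes took at least 99.1% of the counts of every library and ribosomal RNA between 0.128% and 0.296%.

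The tests used the counts. Genes were filtered with edgeR's filterByExpr, which left 16013, and normalised with TMM factors. A quasi-likelihood model (edgeR 4.0.16 in R 4.3.3) with 1 mean per genotype was fitted to all 11 libraries, so that the genotypes shared 1 estimate of the spread; the common biological coefficient of variation was 21.7%. The contrasts compared pairs of genotypes, and a further contrast, the interaction, compared the effect of the nhr-180 mutation between the atfs-1 backgrounds. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. All adjusted p-values of single genes come from this model unless another tool is named. Log2 fold changes are given with standard errors, and levels as CPM, the count scaled by the TMM-adjusted library size, as mean ± SD.

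For gene groups, 45 lists were written down from gene names, and each had at least 5 measured members. Each list was compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and the p-values were adjusted over the lists of a contrast. Camera was repeated with the correlation estimated from the data, and fry was run beside it; fry asks whether the members of a list move on balance one way, without comparing them with other genes. Members were counted by the gene-level test over all genes and adjusted over the list alone. Lists, contrasts, tests, alternatives (apart from a pair named last) and the rule for naming genes were fixed before the data were examined.

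The rule for naming genes took, per pairwise contrast, the 8 largest rises and the 8 largest falls among called genes with a gene-class name, a mean of at least 5 CPM and no overlap between the libraries of the groups compared; up to 3 members with the smallest adjusted p of each called list; and a fixed set of genes including atfs-1, nhr-180, mitochondrial and cytosolic chaperone genes, acdh-1 and vit-2. For the interaction it took the 5 largest coefficients in each direction. Members of the last 2 parts could be left out of the text. Genes outside the rule are marked as chosen after their values were seen.

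Overlaps between contrasts that share libraries were set against 40 simulated runs in which no genotype differed. The model was tested on simulated data drawn from the measured means and library sizes of 16013 genes, with 200 genes changed. In atfs-1(null) against wildtype it recovered 39% of 2-fold and 93% of 4-fold changes. The shares were 28% and 82% for nhr-180 against wildtype, 45% and 90% for the double mutant against atfs-1(null), 29% and 85% for the double mutant against nhr-180, and 37% and 94% for the double mutant against wildtype. False calls made up between 4.2% and 8.33% of the calls in these runs.

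The alternatives were DESeq2 size factors, no filter, the DESeq2 Wald test (DESeq2 1.42.0), a fit of the compared groups only, the replicate number as a block, limma on the deposited TPM values with a pseudocount of 1 or 0.1 and with or without a minimum of 1 TPM in 2 libraries, a minimum fold change, and leaving out each library in turn. A pair of alternatives was added after seeing the data: leaving out both libraries that stood apart on the second principal component, and using the first principal component of the within-genotype residuals as a covariate. No library was left out of the results given in the report.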

Results

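The data consisted of gene counts from whole L4 larvae of 4 genotypes: 3 wildtype samples, 3 atfs-1(null) samples, 2 nhr-180(cmh19) samples and 3 samples of the double mutant. The gene atfs-1 encodes the transcription factor of the mitochondrial unfolded protein response (UPR), and nhr-180 encodes a nuclear hormone receptor. Total counts per library lay between 20860822 and 22921602, and between 19208 and 19775 genes were detected. The wildtype libraries held 22717153, 22465035 and 20860822 counts and the atfs-1(null) libraries 22880659, 22617287 and 22661284. The nhr-180 libraries, replicates 2 and 3, held 22642300 and 22705880, and the double mutant libraries 22773783, 22921602 and 21128015. In the genes named below as the largest rises or falls of a pairwise contrast, all libraries of the first group lay above, or all below, those of the second. This was not required of the other genes said to have risen or fallen, such as the counted list members.

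The targeted genes followed the labels. Transcript of atfs-1 (WBGene00013878, chromosome V from 14193663 to 14197700 in WBcel235) stood at 53.7 ± 1.29 CPM in wildtype (SD, n = 3) and 44.1 ± 4.67 CPM in nhr-180 (n = 2), against 2.71 ± 2.01 CPM in atfs-1(null) (n = 3) and 3.09 ± 0.512 CPM in the double mutant (n = 3). The atfs-1(null) libraries held 10, 99 and 81 counts of atfs-1, and the double mutant libraries 59, 76 and 76, against at least 902 in every other library. Transcript of nhr-180 (WBGene00017961, chromosome V from 665919 to 667510) was scarce, at 3.71 ± 0.573 CPM in wildtype and 4.62 ± 0.455 CPM in atfs-1(null). It stood at 0.338 ± 0.0983 CPM in nhr-180 and 0.494 ± 0.0697 CPM in the double mutant, with 6 to 13 counts per library. The fall of atfs-1 in atfs-1(null) against wildtype was -4.31 ± 0.53 (log2 fold change ± SE, adjusted p = 0.000408), and that of nhr-180 in nhr-180 against wildtype was -3.44 ± 0.29 (adjusted p = 0.00019). The kind of lesion in cmh19 is not given in the sources used here.

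Libraries separated first by atfs-1. On the first principal component, which held 41.9% of the variance, wildtype and nhr-180 libraries lay between -45.8 and -42.8 and libraries lacking atfs-1 between 29.6 and 47.3. On the second component, with 20.5% of the variance, wildtype replicate 2 lay at 43 against 5.2 and 18.5 for the other wildtype libraries, and atfs-1(null) replicate 1 lay at -30.9 against 43 and 31.3. Within wildtype and atfs-1(null) these positions went with germline genes: relative to the wildtype mean, the median of the sperm list was -0.76 (log2) in wildtype replicate 2 and 1.55 in atfs-1(null) replicate 1, and that of the oocyte list was -0.48 and 1.6. Across genotypes the second component did not follow oocyte genes. The nhr-180 libraries lay at -29.5 and -38.2 with oocyte medians of 0.27 and 0.02, and the double mutant libraries at -18.8 to -11.2 with 1.76 to 2.18. Wildtype replicate 3 lay between the other wildtype libraries in 69% of 14038 genes. Correlations of log2 CPM across genes, which are not independent replicates, were 0.96 to 0.993 within genotypes (10 pairs) and 0.935 to 0.983 between them (45 pairs).

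**Figure D1:**
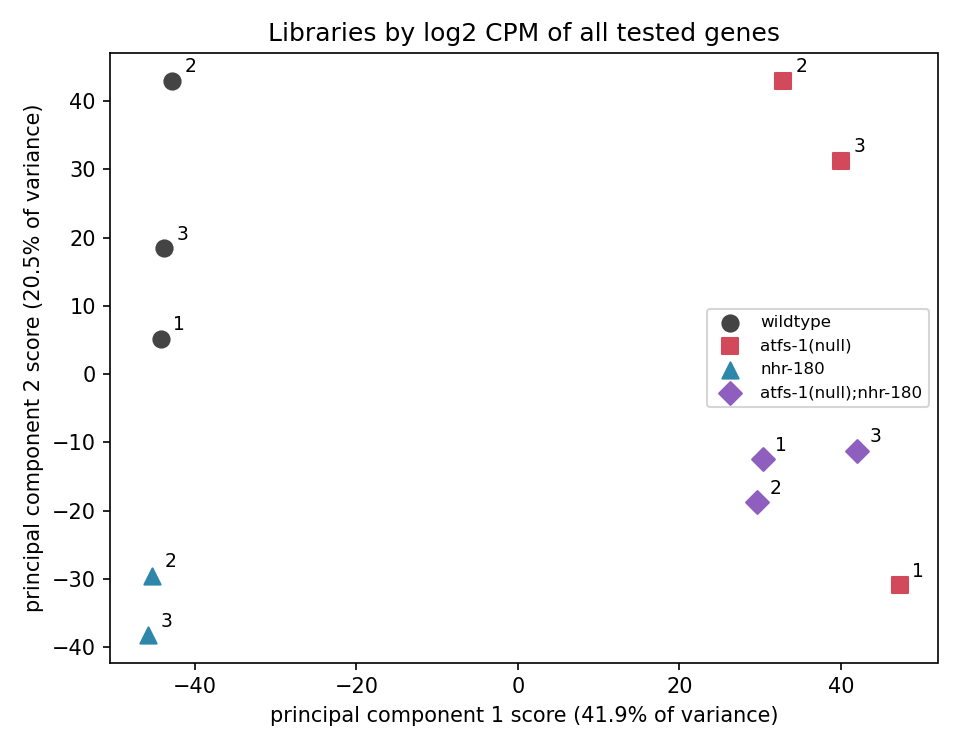
Scores of the 11 libraries on the first (x axis, 41.9% of variance) and second (y axis, 20.5%) principal components of log2 CPM, with colour and marker for genotype and the replicate number beside each point. Libraries lacking atfs-1 lie to the right; wildtype replicate 2 (43 on the second component) and atfs-1(null) replicate 1 (-30.9) lie apart from their groups.

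Loss of atfs-1 on its own was compared with wildtype to ask what the factor controls in animals under no added stress. Several groups of mitochondrial genes had negative medians, though no list was called with an estimated correlation, and the list of genes encoded in mitochondrial DNA was not called at all (adjusted p = 0.269). The mitochondrial Hsp70 gene hsp-6 went from 1002 ± 26.6 CPM in wildtype to 455 ± 121 CPM in atfs-1(null) (n = 3 each), -1.14 ± 0.21 as log2 fold change. Some heat shock genes of the cytosol were higher: the small heat shock protein gene hsp-16.2 went from 1.14 ± 0.552 to 113 ± 18.3 CPM and hsp-16.41 from 0.728 ± 0.305 to 135 ± 24.5 CPM. Yolk protein genes were lower, with vit-2 at 1748 ± 687 CPM in wildtype and 229 ± 98.5 CPM in atfs-1(null).

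Of the 17 measured members of the mitochondrial UPR and proteostasis list, 10 fell and 7 were not called (12 fell adjusted over the list alone). The list was lower with a median of -0.63 and adjusted p = 2.04e-08 (adjusted p = 0.167 with an estimated correlation). Examples were dnj-10, a mitochondrial Hsp40 (-1.03 ± 0.13), hrg-9 (-1.95 ± 0.17) and phb-2, a prohibitin of the inner membrane (-1.06 ± 0.13). The mitochondrial chaperonin gene hsp-60 fell (-0.98 ± 0.23, adjusted p = 0.0179), a call lost without wildtype replicate 1 (0.0573), wildtype replicate 3 (0.0582) or atfs-1(null) replicate 2 (0.0502). Among 13 protein import genes 8 fell (12 adjusted over the list alone), including tomm-70, an outer membrane receptor (-1.15 ± 0.11), and tin-44 (-1.32 ± 0.13). This list had a median of -0.69 and adjusted p = 1.99e-08 (adjusted p = 0.199 with an estimated correlation). Among 71 mitochondrial ribosomal protein genes 41 fell and 30 were not called (56 fell adjusted over the list alone), mrps-31 at -1.15 ± 0.15 and mrps-9 at -0.93 ± 0.12. Their median was -0.55 with adjusted p = 2.19e-21 (adjusted p = 0.265 with an estimated correlation). Of 22 genes of the TCA cycle and pyruvate dehydrogenase 8 fell (11 adjusted over the list alone), pdha-1 and idh-2 at -0.78 each, with adjusted p = 1.09e-06 for the list (adjusted p = 0.226 with an estimated correlation).

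Of the lists for cytosolic translation, that of aminoacyl-tRNA synthetases was called lower (median -0.14, adjusted p = 0.0381, adjusted p = 0.579 with an estimated correlation). No member was called by edgeR over all genes or adjusted over the list alone, while 1 was lower at an unadjusted p under 0.05 and 1 by the DESeq2 Wald test. The call of this list, the cytosolic aminoacyl-tRNA synthetases, was lost without wildtype replicate 1 (0.0741), wildtype replicate 3 (0.0502), atfs-1(null) replicate 1 (0.204) or atfs-1(null) replicate 2 (0.0501). None of the 81 cytosolic ribosomal protein genes was called by edgeR, while 1 was lower at an unadjusted p under 0.05 and 1 by the DESeq2 Wald test. The list was not called (adjusted p = 0.602). The median of 39 translation factors was -0.07 with counts and 0.02 with TPM, and the list was not called (adjusted p = 0.269). In the cytosolic heat shock list 9 of 16 genes rose and 7 were not called (9 adjusted over the list alone), with a median of 0.8 and adjusted p = 1.31e-07 (adjusted p = 0.167 with an estimated correlation). The small heat shock genes hsp-16.41 and hsp-16.2 rose by 7.52 ± 0.35 and 6.62 ± 0.35, and the inducible hsp-70 by 3.2 ± 0.17. The ER chaperone gene hsp-4 was not called (0.28 ± 0.15, adjusted p = 0.238), nor was gst-4, a detoxification enzyme (-0.13 ± 0.17, adjusted p = 0.655). Of 25 autophagy genes 11 rose and 14 were not called (12 rose adjusted over the list alone), with sqst-1, the p62 autophagy receptor, at 1.88 ± 0.16 and lgg-2, of the Atg8 family, at 1.18 ± 0.14 (list adjusted p = 0.000133; adjusted p = 0.167 with an estimated correlation). Of 13 lysozyme genes 6 rose and 1 fell (10 and 2 adjusted over the list alone), lys-7 by 3.53 ± 0.17 (list adjusted p = 0.00188, adjusted p = 0.511 with an estimated correlation). Outside these lists, large rises among genes with a gene-class name and enough reads for the naming rule were those of dod-3 (6.17 ± 0.36), the long noncoding RNA gene tts-1 (5.98 ± 0.31), far-3, a fatty acid and retinol binding protein gene (5.2 ± 0.46), gmd-2 (4.91 ± 0.52), nhr-155 (4.86 ± 0.43) and the C-type lectin gene clec-61 (4.73 ± 0.41).

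All 6 vitellogenin genes fell (6 adjusted over the list alone), with a list median of -4.09 and adjusted p = 1.43e-08 (adjusted p = 0.209 with an estimated correlation). Transcripts of vit-4 went from 205 ± 82.4 to 1.97 ± 1.4 CPM (-6.7 ± 0.67), vit-3 stood at -5.86 ± 0.8, vit-5 at -4.6 ± 0.55 and vit-6 at -3.59 ± 0.46; the first 3 are near-identical copies whose counts are uncertain. Of 151 collagen genes 48 fell and 103 were not called (59 fell and 4 rose adjusted over the list alone), with adjusted p = 6.7e-15 (adjusted p = 0.26 with an estimated correlation). Large falls among them were those of col-179 (-4.24 ± 0.69), col-119 (-4.22 ± 0.62), col-62 (-4.21 ± 0.62) and the adult cuticle collagen gene col-19 (-4.16 ± 0.65). Of 25 molting cycle genes 6 fell and 19 were not called (8 fell adjusted over the list alone), among them wrt-4, of the hedgehog-related family (-2.78 ± 0.41), and mlt-10 (-1.32 ± 0.22), with adjusted p = 3.94e-05 (adjusted p = 0.235 with an estimated correlation). Oocyte genes had a median of 1.07 with 2 of 19 risen (15 adjusted over the list alone), mex-3, an RNA-binding regulator of oocytes, by 1.14 ± 0.23, and adjusted p = 0.000296 (adjusted p = 0.583 with an estimated correlation). The oocyte median was 0.5 without atfs-1(null) replicate 1, and 0.31 without that library and wildtype replicate 2 together, where the list was no longer called (adjusted p = 0.222).

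Body wall muscle markers were lower as a list too (median -0.32, adjusted p = 0.000852; adjusted p = 0.562 with an estimated correlation), with 3 of 15 fallen (3 adjusted over the list alone) and a median of -0.1 without atfs-1(null) replicate 1. Only 1 fell without wildtype replicate 1 or 3. Counts of called list members moved with single libraries. Of the mitochondrial ribosomal proteins 27, 18 and 14 fell without wildtype replicates 1, 2 and 3, and 23 and 21 without atfs-1(null) replicates 2 and 3. Import genes fell in 5 cases without wildtype replicate 2 or 3 or atfs-1(null) replicate 2 or 3, and genes of the TCA cycle in 4, 4 and 3 without wildtype replicates 1, 2 and 3. Autophagy genes rose in 6, 7 and 5 cases without wildtype replicates 1, 2 and 3 and in 7 without double mutant replicate 2. Lysozyme genes rose in 3 cases without wildtype replicate 1 or 3 and in 4 without atfs-1(null) replicate 1. Oocyte genes rose in 15 cases without atfs-1(null) replicate 2, and in 1 without any other library.

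In all, edgeR's quasi-likelihood test called 2291 of 16013 genes in atfs-1(null) against wildtype, 1207 higher and 1084 lower. The count was 1450 without wildtype replicate 1, 1132 without wildtype replicate 3 and 1161 in a fit of these groups only. With the TPM values, whose all-gene median was 0.114 (log2) here, 0.044 in the double mutant against atfs-1(null), 0.11 against nhr-180 and 0.13 against wildtype, the share of called genes that were higher was 64.5% in place of 52.7%.

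The nhr-180 mutation on its own was compared with wildtype in 2 samples against 3. The noncoding RNA tts-1 went from 2.6 ± 0.872 to 62.4 ± 2.2 CPM (4.58 ± 0.31 log2), fmo-2, a flavin-containing monooxygenase gene, from 3.97 ± 0.397 to 50.6 ± 8.33 CPM (3.67 ± 0.19), and kcnl-1, a potassium channel gene, from 9.98 ± 0.43 to 124 ± 8.52 CPM (3.63 ± 0.3). The gene acdh-1, an acyl-CoA dehydrogenase of the propionate shunt that is induced when vitamin B12 is low, fell from 577 ± 108 to 88.9 ± 27.5 CPM (-2.7 ± 0.31). Expression of hsp-6 (-0.66 ± 0.23, adjusted p = 0.168), hsp-60 (-0.54 ± 0.26, adjusted p = 0.292), hsp-16.2 (0.42 ± 0.38, adjusted p = 0.589) and vit-2 (0.67 ± 0.42, adjusted p = 0.409) were not called by edgeR over all groups. The gene hsp-6 was called in a fit of these groups only (-0.63 ± 0.13, adjusted p = 0.0493) and with a covariate chosen after seeing the data (0.00841), but by no other setting.

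Of the 20 cytosolic aminoacyl-tRNA synthetase genes, which load amino acids on tRNAs, none was called by edgeR over all genes or adjusted over the list alone, 10 were lower at an unadjusted p under 0.05, and 4 were lower by the DESeq2 Wald test. The list was lower with a median of -0.36 and adjusted p = 2.96e-07 (adjusted p = 0.225 with an estimated correlation). In it hars-1 stood at -0.42 ± 0.12 (adjusted p = 0.112). Among 39 translation factors none was called over all genes, 13 were lower at an unadjusted p under 0.05, 8 by the DESeq2 Wald test, and 2 fell adjusted over the list alone. Their median was -0.24 with adjusted p = 2.79e-06 (adjusted p = 0.145 with an estimated correlation). Examples were eif-3.E at -0.51 ± 0.13 (adjusted p = 0.0679) and eif-2A at -0.52 ± 0.13 (adjusted p = 0.0762). Both were called without atfs-1(null) replicate 1 (0.0387 and 0.0333) and by the DESeq2 Wald test. The 81 genes of the list of cytosolic ribosomal proteins had a median of -0.15 with adjusted p = 0.000263 (adjusted p = 0.717 with an estimated correlation). None was called by edgeR, 2 differed at an unadjusted p under 0.05 and 1 by the DESeq2 Wald test. Without nhr-180 replicate 2 that median was 0.01 and the list was not called (adjusted p = 0.925), and without nhr-180 replicate 3 it was -0.35.

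The mitochondrial UPR and proteostasis list was lower with a median of -0.43 and adjusted p = 8.37e-05 (adjusted p = 0.265 with an estimated correlation). None of its 17 members was called by edgeR over all genes, 6 were lower at an unadjusted p under 0.05, 5 by the DESeq2 Wald test, and 6 fell adjusted over the list alone. The import gene tomm-70 fell by its own test (-0.72 ± 0.13, adjusted p = 0.0168), but not without wildtype replicate 2 (0.0693), wildtype replicate 3 (0.0827), nhr-180 replicate 2 (0.187) or nhr-180 replicate 3 (0.166). The body wall muscle markers had a median of -0.31 with adjusted p = 0.0331 (adjusted p = 0.711 with an estimated correlation), a call lost without wildtype replicate 1 (0.0906) or nhr-180 replicate 3 (0.0923). None of the 15 was called by edgeR over all genes or adjusted over the list alone, 2 were lower at an unadjusted p under 0.05 and none by the DESeq2 Wald test. In the propionate shunt list 2 of 7 genes fell (5 adjusted over the list alone), 1 of them, hphd-1, not without wildtype replicate 3 (0.0741) or nhr-180 replicate 2 (0.189) or 3 (0.136). The median was -0.45 with adjusted p = 2.79e-06 (adjusted p = 0.145 with an estimated correlation). Of 17 genes of the one-carbon and methionine cycle 4 fell and 1 rose (7 and 1 adjusted over the list alone). All 5 calls were lost without wildtype replicate 2 or 3 or either nhr-180 library, as for sams-1 (0.0693, 0.0741, 0.228 and 0.178) and ahcy-1 (0.0728, 0.0722, 0.209 and 0.0753). Without double mutant replicate 1, 2 or 3 the falls numbered 2, and without atfs-1(null) replicate 1 they numbered 7. Their median was -0.42 with adjusted p = 0.000263 (adjusted p = 0.145 with an estimated correlation). Of 139 C-type lectin genes, many of them induced by pathogens, 10 rose and 2 fell (18 and 3 adjusted over the list alone), clec-61 by 4.45 ± 0.42. The rises numbered 4, 4 and 3 without wildtype replicates 1, 2 and 3, 1 and 3 without nhr-180 replicates 2 and 3, 4 and 5 without double mutant replicates 1 and 2, and 18 without atfs-1(null) replicate 1. This list had adjusted p = 0.000347 (adjusted p = 0.0834 with an estimated correlation). Of 21 pals genes of the intracellular pathogen response 3 rose (6 rose and 1 fell adjusted over the list alone), pals-32 by 2.46 ± 0.25; without nhr-180 replicate 2 only 1 rose. The pals list had adjusted p = 9.43e-05 (adjusted p = 0.172 with an estimated correlation). The smallest p of any list was that of sperm and male germline genes, with a median of 0.71 and adjusted p = 8.6e-11 (adjusted p = 0.603 with an estimated correlation). None of its 73 members was called by edgeR over all genes or adjusted over the list alone, with 16 higher at an unadjusted p under 0.05 and 5 by the DESeq2 Wald test. Its median was 0.39 without wildtype replicate 2, which stood apart on these genes. Replication-dependent histones (median 0.63, adjusted p = 0.000699; adjusted p = 0.653 with an estimated correlation; 1 of 31 rose and 2 adjusted over the list alone) and collagens (0.53, adjusted p = 0.00149; adjusted p = 0.692 with an estimated correlation; 1 of 151 rose and none adjusted over the list alone) were called higher too, the collagens not without nhr-180 replicate 3 (0.117). Without atfs-1(null) replicate 1 the called rises numbered 7 among histones and 16 among collagens. The lipase and lysozyme genes lipl-3 (3.06 ± 0.33), lipl-1 (1.56 ± 0.21) and lys-7 (1.31 ± 0.17) rose.

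Further large rises among genes admitted by the naming rule were those of dod-3 (3.81 ± 0.37), nlp-25, a neuropeptide-like gene next to kcnl-1 on chromosome V (3.56 ± 0.31), pud-3 (3.26 ± 0.46) and pud-4 (3.08 ± 0.49). Large falls among genes with a gene-class name and enough reads for the naming rule were those of srw-85, a chemoreceptor gene with few reads in the nhr-180 libraries (0.135 ± 0.0647 CPM, n = 2), tiar-2, an RNA-binding protein gene (-3.24 ± 0.31), haf-6, an ABC transporter gene (-3.08 ± 0.18), and tbb-6, a beta-tubulin gene (-2.73 ± 0.21). Falls of vnut-1 (-2.06 ± 0.31), dpy-6 (-2.02 ± 0.46) and amt-1 (-1.85 ± 0.42) followed. Without nhr-180 replicate 2 or 3 the calls of vnut-1 (0.0629 and 0.114), dpy-6 (0.296 and 0.325), amt-1 (0.34 and 0.233) and pud-4 (0.0545 and 0.0703) were lost. That of pud-4 was also lost without wildtype replicate 3 (0.0502). The calls of dpy-6 and amt-1, at adjusted p = 0.0491 and 0.0488, were lost as well without wildtype replicate 2 (0.147 and 0.136), wildtype replicate 3 (0.132 and 0.136), atfs-1(null) replicate 3 (0.0634 for both), double mutant replicate 1 (0.0783 and 0.0844) or replicate 2 (0.0596 and 0.0601). The call of dpy-6 was further lost without double mutant replicate 3 (0.0612) and with TPM (0.0737), and that of amt-1 without wildtype replicate 1 (0.0572).

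The test called 358 genes in nhr-180 against wildtype, 252 higher and 106 lower. This count was unstable: it was 146 without wildtype replicate 2, 105 without wildtype replicate 3, 75 and 88 without nhr-180 replicates 2 and 3, 207 and 220 without double mutant replicates 1 and 2, and 1042 without atfs-1(null) replicate 1. It was 907 by the DESeq2 Wald test, 695 with replicate number as a block and 535 in the fit of these groups.

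The double mutant was compared with atfs-1(null) to see what the nhr-180 mutation changes in animals that lack atfs-1, the question the series title points to. Yolk protein genes were higher in the double mutant, where vit-2 and vit-4 overlapped their wildtype levels. Transcripts of vit-2 went from 229 ± 98.5 CPM in atfs-1(null) to 2550.0 ± 770.0 CPM in the double mutant (n = 3 each; 3.48 ± 0.42 log2), and vit-4 from 1.97 ± 1.4 to 145 ± 71.7 CPM (6.2 ± 0.65). The collagen gene col-143 went from 1.43 ± 1.06 to 55.6 ± 29.8 CPM (5.28 ± 0.5). The choline kinase gene ckb-2 fell from 80.7 ± 20.2 to 14.9 ± 2.71 CPM (-2.43 ± 0.2). Mitochondrial chaperone genes did not differ by the test: hsp-6 stood at 455 ± 121 and 523 ± 105 CPM (0.2 ± 0.2, adjusted p = 0.927), hsp-60 at 0.29 ± 0.23 (adjusted p = 0.852), dnj-10 at -0.01 ± 0.13 and hrg-9 at -0.01 ± 0.18 (adjusted p = 0.997 for both), and the cytosolic hsp-16.2 at 0.38 ± 0.26 (adjusted p = 0.784).

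All 6 vitellogenin genes rose (6 adjusted over the list alone), with a median of 4.43 and adjusted p = 7.27e-21 (adjusted p = 0.171 with an estimated correlation). Among them vit-5 rose by 5 ± 0.56, vit-6 by 3.86 ± 0.46 and vit-3 by 5.16 ± 0.78, the last no longer called without atfs-1(null) replicate 3 (0.0794) or double mutant replicate 2 (0.0543). Of 151 collagen genes 7 rose and 144 were not called (24 rose and 5 fell adjusted over the list alone). The rises numbered 40, beside 12 falls, without atfs-1(null) replicate 1, 3 without replicate 2 and 4 without double mutant replicate 2. The median of the collagens was 0.03 with adjusted p = 0.000995 (adjusted p = 0.801 with an estimated correlation), and it was -0.13 and not called without atfs-1(null) replicate 3 (0.12) or double mutant replicate 1 (0.197). The collagen genes that rose most after col-143 were col-8 (4.25 ± 0.56), col-95 (4.12 ± 0.45), col-119 (4.07 ± 0.61) and col-19 (3.56 ± 0.63). Without atfs-1(null) replicate 2 col-8 (0.0691), col-119 (0.132) and col-19 (0.204) were not called. The call of col-119 was also lost without double mutant replicate 2 (0.0636), and col-19, at adjusted p = 0.0414, without any of wildtype replicates 1 and 3, atfs-1(null) replicate 3, the nhr-180 libraries and the double mutant libraries (0.0517 to 0.158).

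Oocyte genes had a median of 1.01 and adjusted p = 7.97e-17 (adjusted p = 0.504 with an estimated correlation). None of the 19 was called by edgeR over all genes, 16 were higher at an unadjusted p under 0.05, 2 by the DESeq2 Wald test and 13 adjusted over the list alone. The oocyte median was 1.58 without atfs-1(null) replicate 1 and 0.66 without replicate 2, and without replicate 1 oma-1 (0.83 ± 0.25, adjusted p = 0.294 with it) and cpg-1 (1.55 ± 0.4, adjusted p = 0.184) were called (0.0162 and 0.0494). In the propionate shunt list 1 of 7 genes fell (3 adjusted over the list alone), with a median of -0.35 and adjusted p = 3.05e-06 (adjusted p = 0.313 with an estimated correlation). That gene was acdh-1 (-1.41 ± 0.26, adjusted p = 0.0448), whose call was lost without wildtype replicate 1 or 3, atfs-1(null) replicate 2, either nhr-180 library or any double mutant library (0.0545 to 0.222). In the ER unfolded protein response list 1 of 18 genes, ckb-2, fell (7 fell and 1 rose adjusted over the list alone), with a median of -0.24 and adjusted p = 4.5e-06 (adjusted p = 0.388 with an estimated correlation); crt-1, calreticulin, stood at -0.5 ± 0.13 and xbp-1, a transcription factor of that response, at -0.45 ± 0.13 (adjusted p = 0.193 and 0.222).

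The cytosolic ribosomal proteins had a median of -0.18 in the double mutant against atfs-1(null), with adjusted p = 6.4e-07 (adjusted p = 0.801 with an estimated correlation). None of the 81 was called by edgeR over all genes, 2 were lower at an unadjusted p under 0.05 and none by the DESeq2 Wald test. In it rps-5 stood at -0.39 ± 0.17 (adjusted p = 0.523). The library that stood apart set this value: without atfs-1(null) replicate 1, where the list median was 0.23 above the wildtype mean against -0.07 and -0.15 in the other atfs-1(null) libraries, the median was -0.04 and the list was not called (adjusted p = 0.414). The median was -0.08 without double mutant replicate 3. Translation factors (median -0.05 with counts, 0.01 with TPM, adjusted p = 0.632) and aminoacyl-tRNA synthetases (0.09, adjusted p = 0.0934) were not called. The mitochondrial UPR and proteostasis list had a median of -0.02 with counts and 0.01 with TPM and was not called.

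The test called 71 genes in this comparison, 50 higher and 21 lower, against 1439 at an unadjusted p under 0.05. Other large falls among genes admitted by the naming rule were those of gakh-1 (-1.19 ± 0.17), cnc-4, of an antimicrobial peptide family (-1.17 ± 0.18), and exc-13 (-1.1 ± 0.17), none of which was called without atfs-1(null) replicate 2 (0.0624, 0.0824 and 0.101), double mutant replicate 1 (0.0506, 0.121 and 0.123) or double mutant replicate 2 (0.0524, 0.0721 and 0.116). The calls of cnc-4 and exc-13 were also lost without wildtype replicate 3 (0.0558 for both) or double mutant replicate 3 (0.0908 and 0.0628), and exc-13 without atfs-1(null) replicate 3 (0.0663). The count was 812 without atfs-1(null) replicate 1, with all 71 genes among them. It was 41 without wildtype replicate 3, 27 and 44 without atfs-1(null) replicates 2 and 3, 47 without either nhr-180 library, and 42 and 31 without double mutant replicates 1 and 2. It was 17 in a fit of these groups only, 150 without the filter and 241 by the DESeq2 Wald test, and the share of higher genes was 80.7% with TPM in place of 70.4%.

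**Figure D2:**
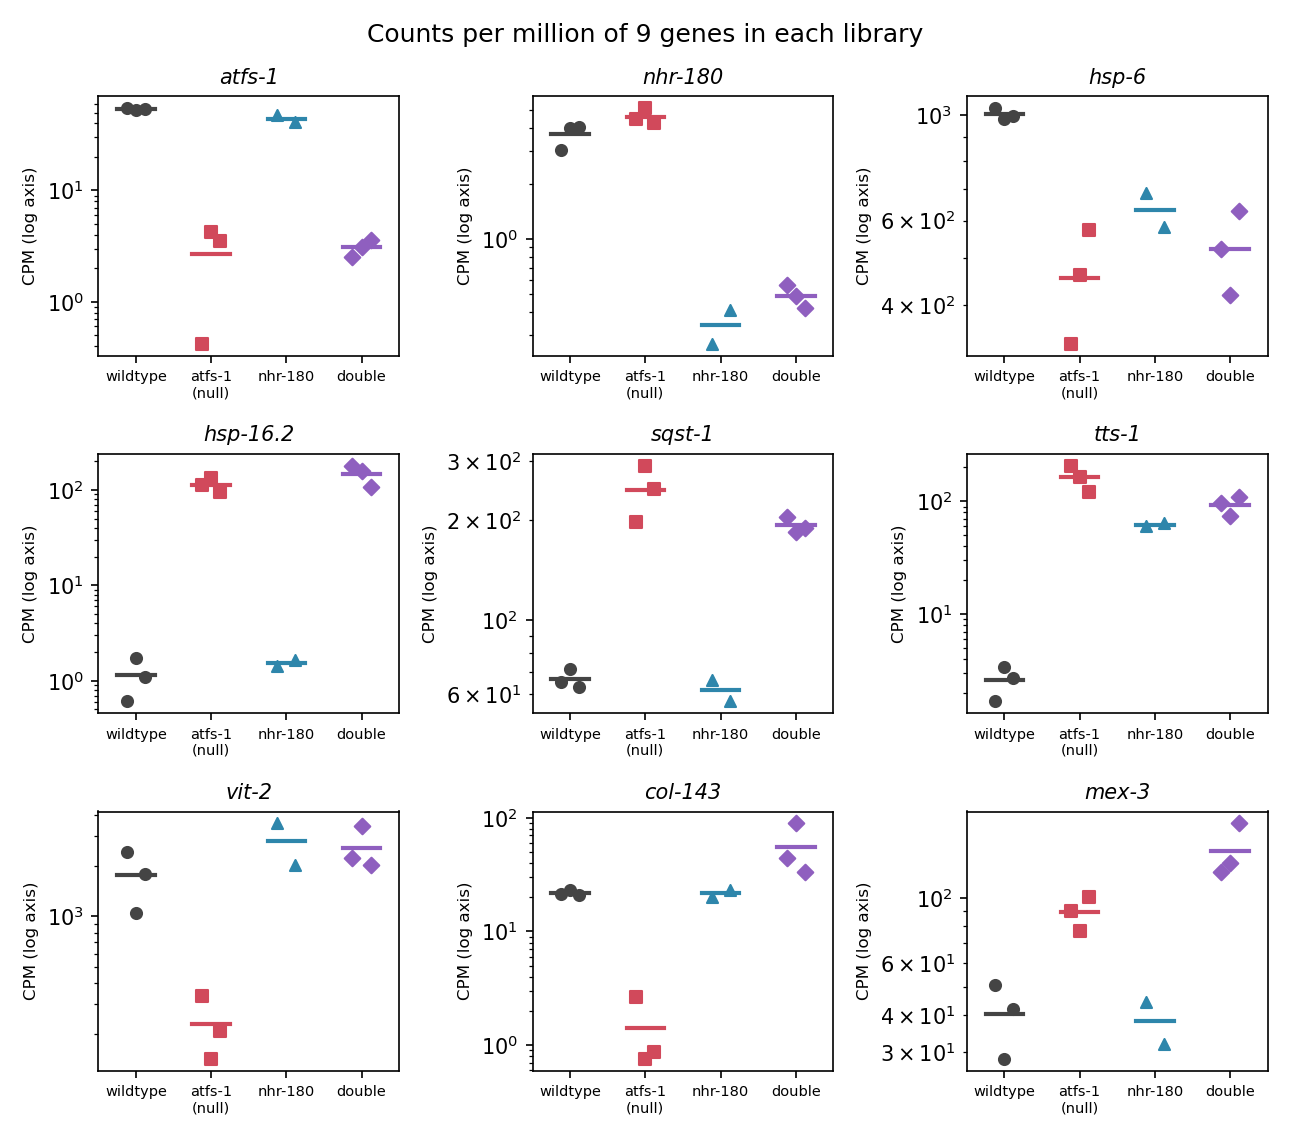
CPM (y axis, log scale) of 9 genes in every library of the 4 genotypes (x axis); points are libraries and lines are group means. Levels of atfs-1 and nhr-180 are low where mutated, hsp-6 is below its wildtype level in every mutant library, hsp-16.2 and sqst-1 are high in all libraries lacking atfs-1, and vit-2 and col-143 are low in atfs-1(null) alone.

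Of the genes called in atfs-1(null) against wildtype, 55 were called in the opposite direction in the double mutant against atfs-1(null), 39 lower then higher and 16 higher then lower. Among the first were vit-2, vit-4, vit-5, vit-6, col-143 and col-119, and among the second ckb-2. These contrasts share the atfs-1(null) libraries, which by itself ties them in opposite directions. In 40 simulated runs without any difference the correlation across genes was -0.5 (-0.34 observed) and the covariance of log2 fold changes -0.048 (-0.123 observed). Sharing wildtype gave a like size there (0.049), though atfs-1(null) replicates varied more (lowest r 0.96 against 0.978), so the excess need not be reversal. How many of the 55 genes sharing alone would give was not measured. Independent lists would give 3.38 and 1.58. In the double mutant against wildtype 41 of the 55 were not called. The count was 340, 22 and 36 without atfs-1(null) replicates 1, 2 and 3. It was 32 without wildtype replicate 3, 37 without either nhr-180 library, and 34 and 26 without double mutant replicates 1 and 2.

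**Figure D3:**
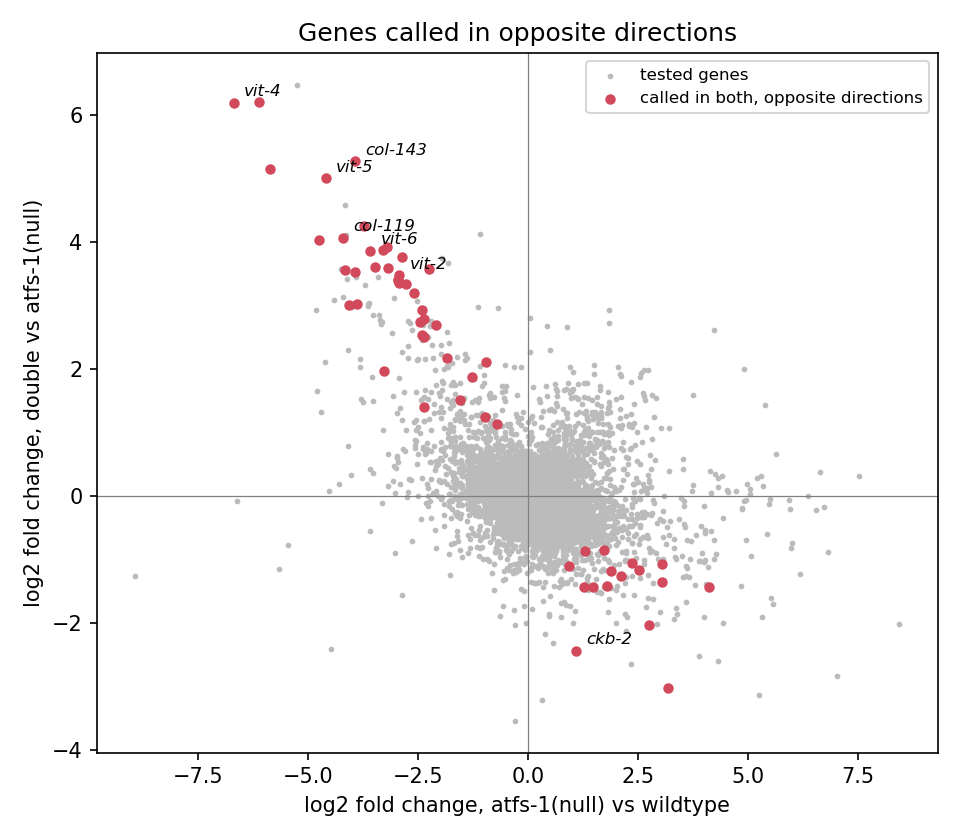
Log2 fold change in atfs-1(null) against wildtype (x axis) and in the double mutant against atfs-1(null) (y axis) for all tested genes (grey); the 55 genes called in both in opposite directions are in red, some with names. Yolk protein and collagen genes lie at the upper left and ckb-2 at the lower right. Both axes use the atfs-1(null) libraries, which ties them.

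The effect of losing atfs-1 was measured a further time, in nhr-180 mutants, by comparing the double mutant with nhr-180 (3 samples against 2). The beta-tubulin gene tbb-6 went from 3.87 ± 0.0337 to 627 ± 88.9 CPM (7.34 ± 0.25 log2), hsp-16.41 rose by 7.13 ± 0.41, hsp-16.2 by 6.59 ± 0.41 and hsp-70 by 3.46 ± 0.21. By their own tests 16 of 19 oocyte genes and 19 of 30 DNA replication genes rose and 59 of 151 collagen genes fell, while none of these lists was called with an estimated correlation (adjusted p = 0.491 for each). Expression of hsp-6 (-0.28 ± 0.23, adjusted p = 0.431), hsp-60 (-0.15 ± 0.26, adjusted p = 0.724) and vit-2 (-0.13 ± 0.42, adjusted p = 0.863) were not called, while hrg-9 fell by 1.66 ± 0.19.

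In the cytosolic heat shock list 12 of 16 genes rose and 4 were not called (12 rose and 1 fell adjusted over the list alone). Their median was 1.12 with adjusted p = 6.73e-10 (adjusted p = 0.125 with an estimated correlation), and it was 2.03 without nhr-180 replicate 3. Of 19 oocyte genes 16 rose (17 adjusted over the list alone), mex-3 by 1.92 ± 0.28. Their median was 1.95 with adjusted p = 6.73e-10 (adjusted p = 0.491 with an estimated correlation). Of 30 genes of DNA replication and the cell cycle 19 rose (27 adjusted over the list alone), including mcm-6, of the replicative helicase (1.09 ± 0.16), cdc-6 (0.88 ± 0.13) and cyclin A, cya-1 (1.02 ± 0.15). Their median was 0.84 with adjusted p = 2.92e-12 (adjusted p = 0.491 with an estimated correlation). Of 151 collagen genes 59 fell and 4 rose (73 and 8 adjusted over the list alone), col-159 at -1.9 ± 0.24 and col-91 at -2.24 ± 0.3. The median was -1.13 with adjusted p = 1.35e-11 (adjusted p = 0.491 with an estimated correlation). Of 41 acyl-CoA dehydrogenase and beta-oxidation genes 14 fell and 2 rose (16 and 3 adjusted over the list alone), acdh-9 at -1.01 ± 0.13 and ech-9 at -2.47 ± 0.27. This list had adjusted p = 0.000858 (adjusted p = 0.491 with an estimated correlation).

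Of 20 aminoacyl-tRNA synthetase genes 4 rose (5 adjusted over the list alone), with a median of 0.25 and adjusted p = 0.00257 (adjusted p = 0.572 with an estimated correlation). The alanyl-tRNA synthetase gene aars-2 rose by 0.64 ± 0.15 (adjusted p = 0.0151), but not without nhr-180 replicate 2 (0.0622) or 3 (0.139). Of 39 translation factors 4 rose (4 adjusted over the list alone), with a median of 0.22 and adjusted p = 0.0151 (adjusted p = 0.491 with an estimated correlation), which was lost without nhr-180 replicate 2 (0.16, adjusted p = 0.176). The cytosolic ribosomal proteins, with 81 genes, had a median of -0.02 with counts and 0.13 with TPM, and the list was not called (adjusted p = 0.802). It was called lower without nhr-180 replicate 2 (-0.17, adjusted p = 0.0019) and higher without replicate 3 (0.17, adjusted p = 0.0107). Of 12 genes encoded in mitochondrial DNA 4 fell (9 adjusted over the list alone), with a median of -0.9 and adjusted p = 0.000309 (adjusted p = 0.597 with an estimated correlation). The mitochondrial UPR and proteostasis list was lower with 3 of 17 genes fallen (3 adjusted over the list alone), a median of -0.34 and adjusted p = 0.00298 (adjusted p = 0.491 with an estimated correlation).

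Counts of called list members were lower without nhr-180 replicate 2 or 3: 7 and 5 risen of the cytosolic heat shock genes, 3 and 1 of the oocyte genes, 8 and 5 of those of DNA replication and cell cycle, and 35 and 17 fallen of the collagens and 7 and 4 of the acyl-CoA dehydrogenase and beta-oxidation genes. The collagens numbered 39 without double mutant replicate 3 and 93 without atfs-1(null) replicate 1. All called members of the aminoacyl-tRNA synthetases, the translation factors and the mitochondrial DNA-encoded genes were lost without either nhr-180 library, the last also without double mutant replicate 3. Synthetase genes rose in 2 cases without wildtype replicate 1, 2 or 3 or double mutant replicate 3 and in 1 without double mutant replicate 1 or 2, and translation factors in 2 without wildtype replicate 3 or double mutant replicate 2 or 3 and in 1 without double mutant replicate 1. Of the mitochondrial DNA-encoded genes 1 fell without wildtype replicate 3 or double mutant replicate 1 and 9 without atfs-1(null) replicate 1, and of the mitochondrial UPR list 1 fell without either nhr-180 library or double mutant replicate 1 and 6 without atfs-1(null) replicate 1.

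Other large rises among genes admitted by the naming rule were those of srw-85 (7.62 ± 0.46), parg-2, a poly(ADP-ribose) glycohydrolase gene (5.87 ± 0.4), nhr-155 (4.62 ± 0.51), cng-1 (4.6 ± 0.41) and far-3 (4.19 ± 0.51). The channel gene kcnl-1 fell (-4.1 ± 0.3), as did asp-8, an aspartyl protease gene (-3.3 ± 0.29), lips-6, a lipase gene (-3.09 ± 0.31), and the collagen gene col-137 (-3.73 ± 0.57). The falls of col-120 (-3.07 ± 0.85), col-60 (-2.94 ± 0.88) and col-152 (-2.93 ± 0.82) were not called without either nhr-180 library or any double mutant library, with adjusted p between 0.0639 and 0.157, and those of col-60 and col-152 not without wildtype replicate 3 (0.0625 and 0.0544). The shunt gene acdh-1 rose (1.88 ± 0.3).

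The test called 2961 genes in the double mutant against nhr-180, 1647 higher and 1314 lower. The count was 843 and 437 without nhr-180 replicates 2 and 3, and 1911, 1819 and 1753 without double mutant replicates 1, 2 and 3. The share of higher genes was 71.7% with TPM in place of 55.6%. Set against atfs-1(null) versus wildtype, with which it shares no library, log2 fold changes correlated across genes with r = 0.6 and rho = 0.5, and 998 genes were called in the same direction (124 higher and 89 lower from independent lists) and 39 in opposite directions. Those counts were 649 and 35 without wildtype replicate 1, 501 and 17 without wildtype replicate 3, 381 and 7 without nhr-180 replicate 2, 277 and 7 without nhr-180 replicate 3, and 635 and 22 without double mutant replicate 1. The effects of nhr-180 in the backgrounds with and without atfs-1 correlated with r = 0.1 and rho = -0.01, with 6 genes called in the same direction and 6 in opposite directions. Independent lists would share 0.787 higher and 0.139 lower genes, and 0.33 and 0.331 in opposite directions. The SE of this r over fits with 1 library left out was 0.17, and how far noise lowers it was not measured. The counts were 1 and 0 without wildtype replicate 3, 3 and 5 without wildtype replicate 2, and 4 and 0 without atfs-1(null) replicate 2. Without atfs-1(null) replicate 1 that correlation was 0.2, with 107 and 30 genes.

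The double mutant was compared with wildtype to see what remained different. Transcripts of hsp-16.2 stood at 148 ± 36.5 CPM against 1.14 ± 0.552 CPM (n = 3 each; 7.01 ± 0.35 log2), sqst-1 at 192 ± 10.7 against 66.5 ± 4.23 CPM (1.53 ± 0.16), and lys-7 at 182 ± 20.3 against 16.6 ± 0.757 CPM (3.46 ± 0.17). Those of hsp-6 remained lower at 523 ± 105 against 1002 ± 26.6 CPM (-0.94 ± 0.21, adjusted p = 0.0122). The chaperonin gene hsp-60 (-0.69 ± 0.23, adjusted p = 0.0655) was called only without atfs-1(null) replicate 1 (0.0211), atfs-1(null) replicate 3 (0.042) or double mutant replicate 3 (0.0191), or under other settings such as the DESeq2 Wald test (0.0226). The yolk protein gene vit-2 was not called (0.54 ± 0.38, adjusted p = 0.346), and neither was the vitellogenin list (median 0.34, adjusted p = 0.753).

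In the mitochondrial UPR and proteostasis list 9 of 17 genes fell (13 adjusted over the list alone), dnj-10 at -1.04 ± 0.13, phb-1 at -0.93 ± 0.12 and hrg-9 at -1.96 ± 0.18. The median was -0.69 with adjusted p = 5e-09 (adjusted p = 0.14 with an estimated correlation). Of 13 import genes 9 fell (13 adjusted over the list alone), tomm-70 at -1.01 ± 0.11, with adjusted p = 1.13e-08 (adjusted p = 0.171 with an estimated correlation). Of 71 mitochondrial ribosomal protein genes 43 fell (55 adjusted over the list alone), with a median of -0.57 and adjusted p = 2.67e-21 (adjusted p = 0.33 with an estimated correlation). Of 45 nuclear genes of the respiratory chain and ATP synthase 9 fell (12 adjusted over the list alone), gas-1, of complex I, at -0.8 ± 0.13. This list had adjusted p = 2.18e-06 (adjusted p = 0.371 with an estimated correlation). The cytosolic ribosomal proteins had a median of -0.17 with adjusted p = 0.000316 (adjusted p = 0.679 with an estimated correlation). None of the 81 was called by edgeR, with 1 at an unadjusted p under 0.05 and 1 by the DESeq2 Wald test. The median was -0.11 without wildtype replicate 2 or double mutant replicate 3.

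Of 19 oocyte genes 17 rose in the double mutant (18 adjusted over the list alone), oma-1 by 1.66 ± 0.26, mex-3 by 1.83 ± 0.24 and cpg-1 by 2.63 ± 0.42. Their median was 2.03 with adjusted p = 4.74e-12 (adjusted p = 0.33 with an estimated correlation). Of 30 DNA replication and cell cycle genes 21 rose (24 adjusted over the list alone), with a median of 0.69 and adjusted p = 1.84e-10 (adjusted p = 0.346 with an estimated correlation). In the cytosolic heat shock list 8 of 16 genes rose (9 adjusted over the list alone), with adjusted p = 1.23e-07 (adjusted p = 0.14 with an estimated correlation). Of 151 collagen genes 32 fell and 4 rose (35 and 4 adjusted over the list alone), with a median of -0.64 and adjusted p = 3.4e-09 (adjusted p = 0.402 with an estimated correlation). In the ER unfolded protein response list 7 of 18 genes fell (8 adjusted over the list alone), ckb-2 at -1.34 ± 0.2, crt-1 at -0.82 ± 0.13 and the protein disulfide isomerase gene pdi-2 at -0.85 ± 0.16. That list had adjusted p = 0.013 (adjusted p = 0.465 with an estimated correlation).

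The list of body wall muscle markers was lower with 4 of 15 fallen (4 adjusted over the list alone), a median of -0.29 and adjusted p = 0.00532 (adjusted p = 0.595 with an estimated correlation). All 4 calls were lost without wildtype replicate 2 or 3 or double mutant replicate 1, and 1 was kept without wildtype replicate 1 or double mutant replicate 2 and 2 without replicate 3. Here too counts of called members moved. Import genes fell in 4 cases without wildtype replicate 2 or 3 or double mutant replicate 1. Of the mitochondrial ribosomal proteins 20 and 18 fell without wildtype replicates 2 and 3, and 21 and 18 without double mutant replicates 1 and 3. Respiratory chain genes fell in 3 cases without wildtype replicate 2 or 3, in 3, 5 and 4 without double mutant replicates 1, 2 and 3, and in 15 without atfs-1(null) replicate 1. DNA replication and cell cycle genes rose in 11 and 9 cases without wildtype replicates 2 and 3 and in 13 without double mutant replicate 3. The collagens fell in 15 and 12 cases without wildtype replicates 1 and 3, 21 and 14 without double mutant replicates 1 and 3, and 65 without atfs-1(null) replicate 1.

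Large rises among genes admitted by the naming rule were those of hsp-16.41 (7.83 ± 0.36), far-3 (5.49 ± 0.46), tts-1 (5.16 ± 0.3), dod-3 (4.95 ± 0.35), gmd-2 (4.84 ± 0.52), clec-61 (4.81 ± 0.41) and nhr-155 (4.67 ± 0.43). Large falls among them were those of asp-8 (-3.42 ± 0.27), the heme-related hrg-2 (-3.02 ± 0.2), haf-6 (-2.84 ± 0.15), rips-1 (-2.32 ± 0.31), tiar-2 (-2.16 ± 0.25) and the glucuronosyltransferase genes ugt-19 (-2.27 ± 0.17) and ugt-62 (-2.11 ± 0.13). The test called 2618 genes, 1614 higher and 1004 lower. The count was 1480 and 1121 without wildtype replicates 2 and 3, 1618, 1532 and 1431 without double mutant replicates 1, 2 and 3, and 4069 without atfs-1(null) replicate 1. The share of higher genes was 78% with TPM in place of 61.7%. Of the 2291 genes called in atfs-1(null) against wildtype, 1502 were called in the same direction here, 785 were not called and 4 were called in the opposite direction. The shared count was 990, 914 and 669 without wildtype replicates 1, 2 and 3, and 925, 997 and 967 without double mutant replicates 1, 2 and 3. Both contrasts use the wildtype libraries: r was 0.83 against 0.51 in simulated runs without any difference, the covariance 0.497 against 0.049, and independent lists would share 122 higher and 68 lower genes.

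**Figure D4:**
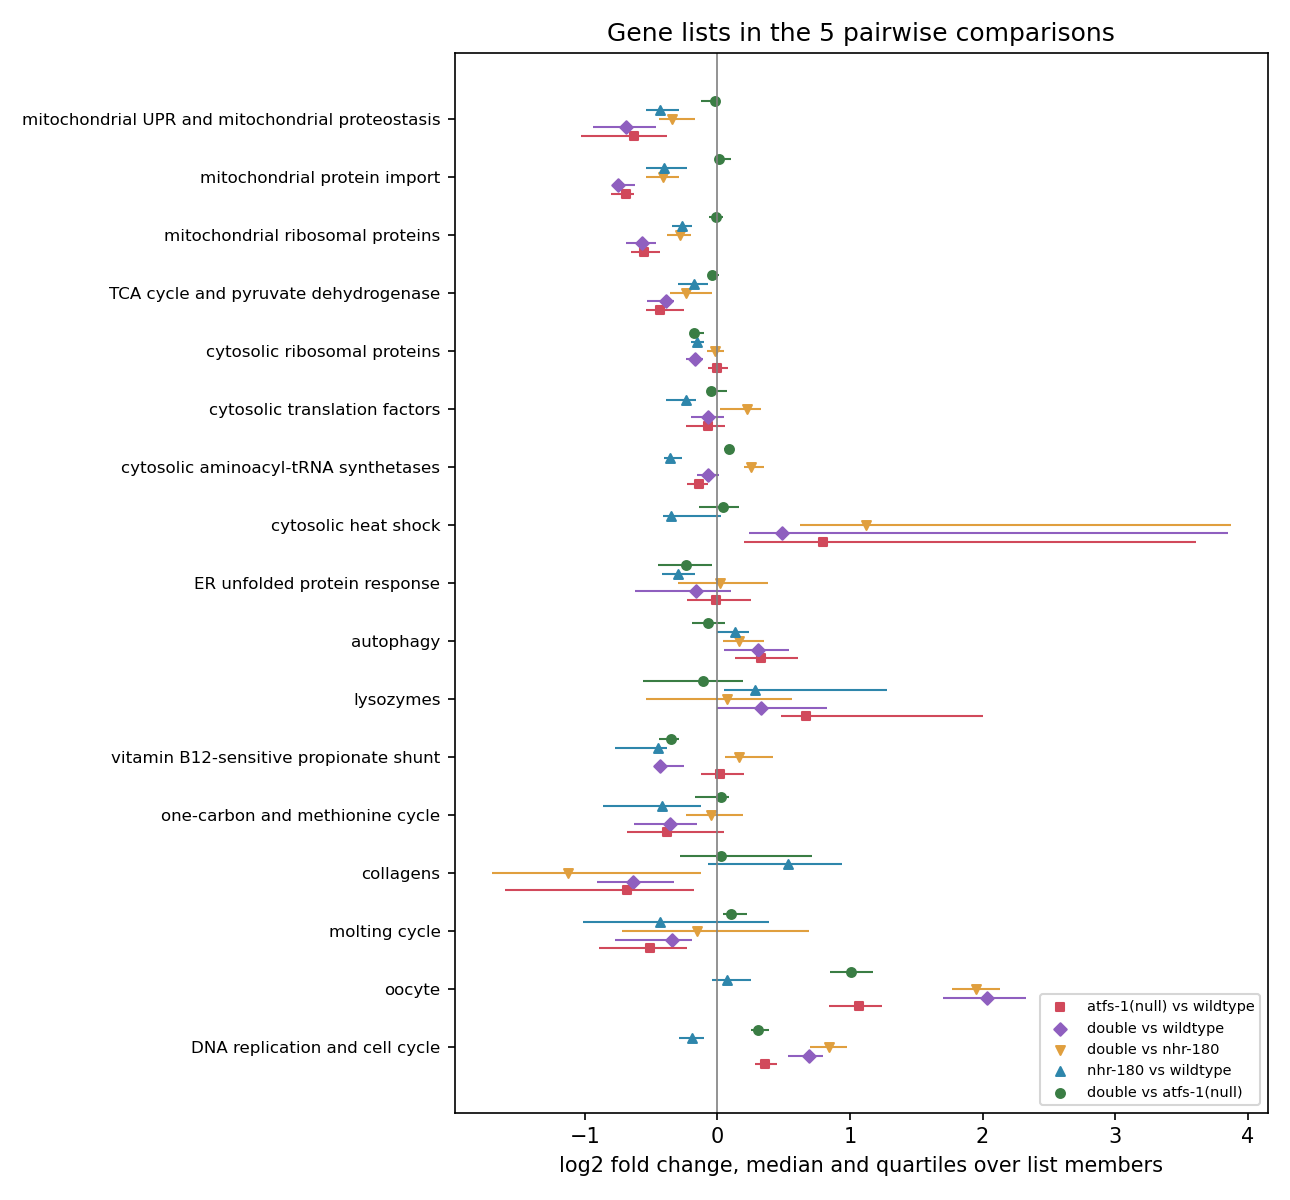
Median log2 fold change (points, x axis) with quartiles (lines) over the members of 17 gene lists (y axis) in the 5 pairwise comparisons. The 4 mitochondrial lists shown lie below 0 against wildtype in all mutants (that of genes encoded in mitochondrial DNA, not shown, lay at 0.28 in nhr-180); medians near 0 change sign with TPM, as for cytosolic ribosomal proteins in the double mutant against nhr-180 (-0.02 and 0.13).

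The interaction contrast asked whether the effect of the nhr-180 mutation differed between animals with and without atfs-1. It called 182 genes, 44 with a positive and 138 with a negative difference. The RNA tts-1 was 4.58 ± 0.31 (log2) higher with the nhr-180 mutation in animals with atfs-1 and stood at -0.82 ± 0.25 in animals without it, a difference of -5.4 ± 0.39 (adjusted p = 0.000113). Differences of dod-3 (-5.03 ± 0.45), clec-61 (-4.37 ± 0.53), clec-52 (-4.31 ± 0.53) and kcnl-1 (-3.99 ± 0.4) followed. On the positive side stood vit-4 (6.03 ± 0.88), srw-85 (5.94 ± 0.53), col-143 (5.29 ± 0.68), vit-5 (4.49 ± 0.77) and tiar-2 (3.36 ± 0.39). The call of vit-4 was not kept without nhr-180 replicate 2 (0.0625) or 3 (0.0992), nor was that of vit-5 (0.1 and 0.165), the latter also not without wildtype replicate 3 (0.0646).

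By list, the interaction was positive for the aminoacyl-tRNA synthetases (median 0.46, adjusted p = 4.03e-07; adjusted p = 0.241 with an estimated correlation) and the translation factors (0.22, adjusted p = 0.000541; adjusted p = 0.241 with an estimated correlation). No member of either was called by edgeR, with 10 and 8 positive at an unadjusted p under 0.05 and 1 and 3 by the DESeq2 Wald test. It was positive for the vitellogenins, with 3 of 6 called (6 adjusted over the list alone; 1 without wildtype replicate 3, 6 without atfs-1(null) replicate 1 and all calls lost without either nhr-180 library), a median of 3.83 and adjusted p = 1.77e-08 (adjusted p = 0.241 with an estimated correlation). It was negative for the pals genes, with 3 of 21 called (7 negative and 1 positive adjusted over the list alone), a median of -0.68 and adjusted p = 4.22e-05 (adjusted p = 0.241 with an estimated correlation), and for the C-type lectins, with 3 of 139 called (7 negative and 1 positive adjusted over the list alone) and adjusted p = 0.00116 (adjusted p = 0.133 with an estimated correlation). Only 1 of the pals genes was called without wildtype replicate 2, atfs-1(null) replicate 2, either nhr-180 library or double mutant replicate 1 or 2, and 7 lectin genes were called negative and 3 positive without atfs-1(null) replicate 1. Cytosolic ribosomal protein genes had a median of -0.01 with counts and 0.05 with TPM. The number of called genes was 103, 113 and 68 without wildtype replicates 1, 2 and 3, 456 and 101 without atfs-1(null) replicates 1 and 2, 65 and 67 without nhr-180 replicates 2 and 3, and 88, 83 and 119 without double mutant replicates 1, 2 and 3. It was 488 by the DESeq2 Wald test.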

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

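The tests of explanations in this part were chosen only after the result was seen, apart from the counts of calls in other splits of the samples, which were set before.

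The interaction contrast in edgeR called 29 of the 109 named genes, 12 in the positive and 17 in the negative direction. Over all genes it called 182 of 16013, and the naming rule itself took the largest differences, so the share among named genes measures nothing. Values are log2 differences, the effect in animals without atfs-1 minus that in animals with it. The positive ones were vit-4 (6.03), srw-85 (5.94), col-143 (5.29), vit-5 (4.49), col-95 (3.67), tiar-2 (3.36), haf-6 (3.32), vit-6 (3.17), tbb-6 (2.8), amt-1 (2.71), vnut-1 (1.98) and tomm-70 (0.86). In vit-4, vit-5, vit-6, col-95 and col-143, yolk protein and collagen genes, nhr-180 against wildtype was not called and the double mutant was above atfs-1(null). In srw-85, tiar-2, haf-6, tbb-6, amt-1, vnut-1 and tomm-70 the fall stood in nhr-180 against wildtype, with no call in the double mutant against atfs-1(null). That fall is not particular to nhr-180 for tiar-2, haf-6, amt-1, vnut-1 and tomm-70, which fell in atfs-1(null) against wildtype as well (-2.28, -3.08, -2.55, -1.72 and -1.15), so that wildtype alone was high, whereas srw-85 and tbb-6 rose there (1.68 and 4.54).

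The negative ones were tts-1 (-5.4), dod-3 (-5.03), clec-61 (-4.37), clec-52 (-4.31), kcnl-1 (-3.99), lipl-3 (-3.75), fmo-2 (-3.55), pud-4 (-3.55), pud-3 (-3.42), nlp-25 (-3.01), ech-9 (-2.77), pals-32 (-2.21), ckb-2 (-1.98), lipl-1 (-1.65), lys-7 (-1.38), gakh-1 (-1.29) and lgg-2 (-1.02). All of them except ckb-2 and gakh-1 were called higher in nhr-180 against wildtype, and ckb-2 and gakh-1 were called lower in the double mutant against atfs-1(null). Of those higher in nhr-180, all but kcnl-1, nlp-25 and ech-9 were called higher in atfs-1(null) against wildtype as well, so that wildtype alone was low. A wildtype stock differing from those of all mutants could give the calls where wildtype alone stood apart, and this was not tested.

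Several of these calls were lost with 1 library left out, many of them whichever of several libraries it was. Without nhr-180 replicate 2 or 3 the adjusted p was 0.0625 and 0.0992 for vit-4, 0.1 and 0.165 for vit-5, 0.155 and 0.151 for col-95, 0.139 and 0.28 for vit-6, 0.178 and 0.188 for tomm-70, 0.215 and 0.165 for amt-1, and 0.141 and 0.25 for vnut-1. It was 0.18 and 0.134 for lgg-2, 0.18 and 0.122 for gakh-1, 0.0969 and 0.086 for lys-7, 0.117 and 0.07 for lipl-1, 0.1 and 0.109 for pud-3, and 0.0969 and 0.129 for pud-4. The call of ckb-2 was lost without nhr-180 replicate 3 (0.0633). Without wildtype replicate 3 all of these but vit-4 and ckb-2 were lost too (0.0646 for vit-5, 0.0919 for col-95, 0.114 for vit-6, 0.126 for tomm-70, 0.117 for amt-1, 0.112 for vnut-1, 0.11 for lgg-2 and gakh-1, 0.0706 for lys-7 and lipl-1, 0.0865 for pud-3 and 0.0845 for pud-4). Most of them were lost without other single libraries as well: col-95, vit-6, tomm-70, amt-1, vnut-1, lgg-2, gakh-1, lys-7, lipl-1, pud-3 and pud-4 without wildtype replicate 1 (0.0524 to 0.0857), and vit-6, tomm-70, amt-1, vnut-1, lgg-2, gakh-1, lys-7, lipl-1, pud-3 and pud-4 without double mutant replicate 1 (0.0555 to 0.116) or 2 (0.0589 to 0.118).

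Without double mutant replicate 3, vit-6 (0.0616), tomm-70 (0.0668), vnut-1 (0.0581), lgg-2 (0.0742), lipl-1 (0.0587), pud-3 (0.0668) and pud-4 (0.0723) were lost. Wildtype replicate 2 left out cost tomm-70 (0.102), amt-1 (0.098), vnut-1 (0.0807), lgg-2 (0.0752), gakh-1 (0.0843), pud-3 (0.0515) and pud-4 (0.0639). Omitting atfs-1(null) replicate 2 cost col-95 (0.0789), vit-6 (0.0818), tomm-70 (0.0897), amt-1 (0.053), vnut-1 (0.0983), lgg-2 (0.0916) and gakh-1 (0.0844), and omitting replicate 3 cost col-95 (0.0537), vit-6 (0.0887), tomm-70 (0.0512), amt-1 (0.076), lgg-2 (0.058) and gakh-1 (0.0718). With TPM, pals-32 (0.0578), tomm-70 (0.0656), vnut-1 (0.0656), lgg-2 (0.0942) and gakh-1 (0.139) were not called. With replicate number as a block, vit-5 (0.0506), col-95 (0.0548), vit-6 (0.0625), tomm-70 (0.0684), lgg-2 (0.0825), amt-1 (0.0534) and gakh-1 (0.0687) were not called either. The call of tomm-70 was also lost without the filter (0.12) and without both libraries that stood apart (0.0552), and that of amt-1 with TPM and a pseudocount of 0.1 (0.0717).

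The first pattern weighed is the yolk protein genes, low in atfs-1(null) and higher in the double mutant. It does not rest on 1 library, since the vitellogenin median of the double mutant against atfs-1(null) was at least 4.08 with any library left out. A later stage of the double mutant than of atfs-1(null) would raise oocyte genes. Their median was 1.01 in that contrast, though the list was not called with an estimated correlation (0.504). By library, oocyte medians relative to the wildtype mean were -0.48 to 0.48 in wildtype and nhr-180, 0.19 to 1.6 in atfs-1(null) and 1.76 to 2.18 in the double mutant. Vitellogenin medians were -0.66 to 0.96, -5.25 to -3.51 and -0.04 to 0.89. Stage as read from oocyte genes did not order the yolk levels. The adult collagen gene col-19 followed them (-4.16 against wildtype, then 3.56), the collagen list did not (-0.68, then 0.03). A later double mutant stays open. An earlier stage of atfs-1(null) than of wildtype would lower oocyte genes there too, but their median was 1.07, a call lost with an estimated correlation (0.583), so this stays open. The vitellogenin median differed by 1.74 between atfs-1(null) libraries. That spread did not reach the gap to all other libraries (-3.51 or lower against -0.66 or higher). An effect of genotype on yolk genes and a time of collection that differed with genotype still cannot be told apart.

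The second pattern is wildtype replicate 3, which lay between replicates 1 and 2. Combined reads of those libraries were excluded, because the chi-square per degree of freedom of replicate 3 against their best weighted sum was 2.53 (SE 0.248), where shared reads gave 0.322 in simulated data. RNA or worms of both pooled before library making remain possible, although 2.53 also exceeds the 0.999 of a simulated mix with counting noise alone. Libraries of other genotypes gave at least 17.2. Wildtype replicates 1 and 2 against the other wildtype libraries gave 2.72 and 3.01, with a negative weight in each sum (-0.495 and -0.888). The low value thus holds for wildtype as a group and does not by itself mark replicate 3 as a pool. Separate cultures that differ along 1 axis of timing could also place replicate 3 between the others, as it was in 69% of genes, and this stays open too. If replicate 3 is not independent, p-values against wildtype and of the interaction are too small, and as the spread is shared over all libraries the other contrasts carry the doubt too: without it the count was 68 for the interaction, and 41 and 2125 for the double mutant against atfs-1(null) and nhr-180.

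The third pattern is a set of 9 genes at least 4-fold lower than wildtype in every mutant group, among them haf-6, tiar-2 and BE0003N10.6, the last at 71.1 CPM in wildtype, 0.723 in atfs-1(null), 1.78 in nhr-180 and 0.691 in the double mutant; genes outside the naming rule were chosen after their values were seen. The 6 genes on other chromosomes cannot themselves be linked to the mutated loci, both on chromosome V. Their positions do not exclude a variant linked to those loci that acts on genes elsewhere, which was not tested. For the 3 on chromosome V linkage stays open, the nearest lying 2.69 Mb from either locus. Some of the 9 lie close together. On chromosome II nhr-234, nhr-235 and tiar-2 start at 12636678, 12640670 and 12768686, and on chromosome V D1014.7 and D1014.6 start at 8118264 and 8121168. A wildtype stock that differs from the stocks of all mutants is a candidate explanation, as 4 of the 9 differed between no pair of mutant groups, but shared effects of the mutations cannot be told apart from it without further wildtype stocks.

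For the 6 libraries of each of 3 comparisons, 10 splits are possible, too few for a share under 0.05. In atfs-1(null) against wildtype the real split called 2291 genes and 1 of the 10 splits called as many; the highest of the others was 0, with up to 2050.0 genes at an unadjusted p under 0.05 in edgeR. In the double mutant against wildtype the values were 2618, 1 of 10 and 0, with up to 1081 at an unadjusted p under 0.05. In the double mutant against atfs-1(null), where the real split called 71 genes, 2 of the 10 splits called as many, and the highest other called 409 (4157 against 1439 at an unadjusted p under 0.05). That split set atfs-1(null) replicate 1 and double mutant replicates 1 and 2 against the rest, which points to a structure of the samples other than genotype.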

How the results depend on the processing

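Leaving out both libraries that stood apart, and the covariate, were chosen after seeing the data. Of 209 called named-gene results, 169 kept their call under every alternative set beforehand, 170 in every fit with 1 library left out, and none turned direction in edgeR, DESeq2 or limma. Counts moved more, and except where the construction shows it (fewer libraries or genes, or a covariate taken from the same residuals, which lowers the spread) the cause was not tested.

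In the order atfs-1(null) against wildtype, nhr-180 against wildtype, double mutant against atfs-1(null), against nhr-180 and against wildtype, and interaction, counts with 1 library left out ran from 1132 to 2408, 75 to 1042, 27 to 812, 437 to 4332, 1121 to 4069 and 65 to 456. With 1 nhr-180 library left out, the other is assumed to vary like the remaining groups. Without both libraries that stood apart, nhr-180 against wildtype gave 555, the double mutant 982 against atfs-1(null) and 4643 against nhr-180, the interaction 482 and opposite-direction genes 404. With the covariate the counts were 4595, 1491, 296, 5565, 5028 and 1150, and 192 opposite-direction genes. The DESeq2 Wald test gave 907 for nhr-180 against wildtype, 241 for the double mutant against atfs-1(null), 488 for the interaction and 158 opposite-direction genes. No filter gave 150 for the double mutant against atfs-1(null), 114 opposite-direction genes and an across-gene correlation of the atfs-1 effects of 0.25. Fits of the compared groups gave 1161 for atfs-1(null) against wildtype and 17 for the double mutant against atfs-1(null), unfiltered TPM 113 for the latter, and a minimum fold of 2 gave 1176, 1477 and 1177 for atfs-1(null) against wildtype and the double mutant against nhr-180 and wildtype. Opposite-direction genes ran from 22 to 340 with 1 library left out. Replicate number as a block gave 695 for nhr-180 against wildtype. Within-genotype residuals of same-number pairs correlated above 0.1 in 5 of 15 cases, with values of -0.41 to 0.613 over all 15. Of 11 libraries 5 correlated best with their own number. Residuals within groups this small are tied to each other, so these values cannot decide whether the numbers pair the samples.

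Camera with an estimated correlation called 0 of 45 lists in each contrast, with 9, 7, 4, 3, 7 and 6 at an unadjusted p under 0.05, and fry called 12 in nhr-180 against wildtype, 3 in the double mutant against atfs-1(null) and 8 in the interaction, fewer than camera's 27, 16 and 27. The interaction of the sperm list turned from -0.52 to 0.19 without both libraries that stood apart. Depth limits the low-level genes: nhr-180 itself had 6 to 13 counts in libraries carrying its mutation.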

Other observations

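The genes named in this part, several outside the naming rule, and the tests on them were chosen only after their values were seen.

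Some genes were higher in all 3 mutant groups than in wildtype: 118 genes were called higher and 40 lower in atfs-1(null), nhr-180 and the double mutant alike. These counts were 63 and 15 without wildtype replicate 2, 43 and 12 without wildtype replicate 3, 36 and 6 without nhr-180 replicate 2, 36 and 11 without nhr-180 replicate 3, 76 and 23 without double mutant replicate 1, 76 and 28 without replicate 2, and 166 and 80 without atfs-1(null) replicate 1. All 3 contrasts use the wildtype libraries, which ties them. In atfs-1(null) and nhr-180 against wildtype 189 genes were called in the same direction and 28 in opposite directions, where independent lists would share 19 higher and 7.18 lower genes. Those counts were 96 and 7 without wildtype replicate 2, 66 and 4 without wildtype replicate 3, 51 and 3 without nhr-180 replicate 2, 56 and 4 without nhr-180 replicate 3, 284 and 149 without atfs-1(null) replicate 1, 157 and 15 without replicate 3, and 129 and 11, and 134 and 13, without double mutant replicates 1 and 2. The correlation across genes, 0.25, was below the 0.45 that shared libraries alone gave in simulated data, while the covariance was 0.117 against 0.049. The alcohol dehydrogenase gene adh-1 stood at 2.67 ± 0.27 (log2 ± SE) in atfs-1(null), 2.9 ± 0.29 in nhr-180 and 2.78 ± 0.27 in the double mutant, and scl-2 at 3.36 ± 0.28, 2.59 ± 0.29 and 2.36 ± 0.27. The gene fmo-2 rose by 2.71 ± 0.17 in atfs-1(null) and 2.83 ± 0.17 in the double mutant, and pud-3 by 3.55 ± 0.44 and 3.4 ± 0.44.

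The mitochondrial ribosomal RNA genes MTCE.7 and MTCE.33 had more reads in libraries lacking atfs-1. Ribosomal RNA took at most 0.296% of counts, a remnant that need not follow its level. MTCE.7 stood at 9.35 ± 2.17 CPM in wildtype (SD, n = 3) and 12.2 ± 2.33 in nhr-180 (n = 2), against 110.3 ± 32 in atfs-1(null) and 78.8 ± 24.1 in the double mutant (n = 3 each). It rose by 3.56 ± 0.3 in atfs-1(null) against wildtype and by 2.69 ± 0.34 in the double mutant against nhr-180. MTCE.33 rose by 2.59 ± 0.3 and 1.59 ± 0.34, the latter not without nhr-180 replicate 2 (adjusted p = 0.0951) or 3 (0.0744). The list of mitochondrial DNA-encoded genes, all protein-coding, had a median of -0.9 in the double mutant against nhr-180 (adjusted p = 0.000309; 0.597 with an estimated correlation), and was not called in atfs-1(null) against wildtype (-0.14, adjusted p = 0.269). It was called lower in the double mutant against atfs-1(null) (-0.37, adjusted p = 0.000469; 0.801 with an estimated correlation), but not without atfs-1(null) replicate 1 (0.322). Medians of the atfs-1(null) libraries were 0.35, -0.22 and -0.58.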
